A study of Homo sapiens with 6 samples.

How the data were processed

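Guide abundance was measured in sorted cells of a pooled CRISPR knockout screen. The cells were A549, an established human lung cancer line that responds to glucocorticoids through the glucocorticoid receptor. Per the labels' protocols, the lentiviral Brunello library, a genome-wide collection of Cas9 guide RNAs with mostly 4 guides per gene, was delivered at a multiplicity of about 0.3. Infected cells were selected with puromycin at 2 µg/mL for 3 days and grown for 14 days. They were then kept in charcoal-stripped serum for 24 hours and given hydrocortisone at 1 µg/mL for 24 hours. Fixed cells were stained with an antibody to FKBP5, a protein whose gene is switched on by the hormone-bound receptor, and the 7.5% of cells with the lowest and the 7.5% with the highest staining were sorted. The labels state about 3500000 cells per sorted fraction. Guides were amplified from genomic DNA by PCR and sequenced. The labels describe 3 biological replicates of each fraction, so 6 libraries form the groups FKBP5low and FKBP5high.

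The authors deposited a table of counts, whole reads per guide and library, for 76933 guides. The lowest value in the table is 1, so a guide without reads is listed at 1. Whether 1 was added to every count or only zeros were raised could not be read from the values. The authors also deposited scaled values, a score obtained by multiplying each library by 1 factor between 0.995 and 1.273 and rounding up, which brings the totals to between 14.38 and 14.41 M. In a further table deposited by the authors, the scaled values of the 3 libraries of a fraction are summed, which held for all 76933 guides. Per the submitters' processing notes, MAGeCK and the genome build GRCh38 were used; versions and the read counter are not given in the sources used here. The gene table the authors deposited holds MAGeCK scores, p-values with false discovery rates, ranks and log2 fold changes, and its fold changes correlate with the low over high ratio of the pooled table across genes at r = 0.999. Positive values in it mean more guide in FKBP5low.

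The table names 19112 gene symbols and 998 non-targeting guides, and 18627 symbols have 4 guides. Symbols altered to calendar dates, 26 with 112 guides, were left out of the gene tests. Of the symbols, 17852 are current in the RefSeq table of assembly GRCh38.p14, 1090 matched through a synonym and 170 had no match. Gene positions are from that table. No guide was placed on the genome, because no genome sequence was used here.

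Totals per library ran from 11.29 to 14.44 M counts, so 1 count was worth between 0.0692 and 0.0886 counts per M of the library total. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. A fold against a group at 1 in each library was computed against 3 counts per library and is given as a lower bound.

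The following choices were made before the data were examined. Guides with at least 10 counts in at least 3 libraries, 52508 in all, were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, robust) in R 4.3.3, FKBP5low against FKBP5high, without a block. A gene test by robust rank aggregation (RRA) after the principle of MAGeCK was written for this work in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. It ranks guides by the 1-sided edgeR p with alpha 0.25, compares each gene with 2000000 random guide sets of the same size, and adjusts by Benjamini-Hochberg in each direction over the 16124 genes with at least 2 tested guides. The smallest p those random sets can give is 5e-07. The threshold was an adjusted p of 0.05 throughout. Gene differences and their standard errors (SE) are from limma 3.58.1 on the mean log2 CPM of a gene's tested guides, with a prior count of 2. Summed CPM (counts per M of the TMM-scaled total of tested guides) add all guides of a gene, tested or not, and are given as mean ± SD.

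Of 26 gene lists fixed in advance, 25 had at least 3 tested genes and were tested with camera of limma at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The lists were the antigen and receptor, receptor chaperones, glucocorticoid transport and metabolism, nuclear receptor coactivators, nuclear receptor corepressors, Mediator, SWI/SNF, cohesin and CTCF, the MLL3/4 (KMT2C/D) complex, the MLL1/2 and SET1 complexes, SAGA, Polycomb repressive complex 2, enhancer transcription factors, transcription elongation, mTORC1, the EGFR-RAS-MAPK pathway, the p53 pathway, KEAP1-NRF2, the G1/S cell cycle, the Hippo pathway, m6A writers and nonsense-mediated decay, cytosolic ribosomal proteins, mitochondrial complex I, the proteasome, the mitochondrial ribosome and olfactory receptors. The genes named are NR3C1, FKBP5, PAXIP1 and STAG2 always. To these come, per direction, up to 12 genes past the threshold with the smallest p and at least 3 guides in that direction, or, where fewer than 5 pass, the 5 with the smallest p. From each list come the members past the threshold and up to 3 examples with the smallest p; 1 such example is not reported here. The guides named are those of the always-named genes and the 3 with the smallest p in each direction.

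The labels number the replicates 1 to 3 in both groups. Deviations from the group means correlated across guides at 0.573, 0.553 and 0.543 between same-numbered FKBP5low and FKBP5high libraries and at -0.298 to -0.247 between differently numbered ones. The numbers therefore pair the libraries by the rule set in advance (a correlation over 0.1 in every pair), and values from the fit with the replicate number as a block (the replicate block) are given where they change a call or move a count by over 1.5 times. The common dispersion was 2.081 without and 1.092 with the block.

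Alternatives covered other normalizations, DESeq2 1.42.0, the count filter, leaving out libraries, other gene tests, other thresholds, the authors' scaled values with limma, and the list test. Some were added after the data had been seen: counts minus 1, bias-adjusted deviances, and combinations with the replicate block. Where libraries were left out, the filter of at least 10 counts in at least 3 libraries was applied again to those that remained. The guide, gene and list tests were tested on simulated counts with known answers, drawn from the means of the real library pairs with a dispersion of 1 and 200 changed genes. For FKBP5low against FKBP5high with 16353 genes tested, 25 of 87 genes with a log2 fold of 4 were recovered without the block (28.7%) and 44 with it (50.6%), and 3 of 86 genes with a log2 fold of 2 without it (3.5%) and 4 with it (4.7%). Calls numbered 31 and 51, of which 3 and 3 were false, and 2 and 6 of 100 random lists had a camera p under 0.05. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3.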

Results

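The screen asked which genes the glucocorticoid receptor needs as co-regulators in A549 cells treated with hydrocortisone, with the level of FKBP5 protein as the readout. A guide that is more abundant in FKBP5low cells than in FKBP5high cells marks a gene whose disruption went with less FKBP5 staining. The FKBP5low libraries of replicates 1, 2 and 3 held 14.44, 11.29 and 14.41 M counts, and the FKBP5high libraries 12.75, 12.03 and 12.83 M. Guides listed at 1, the lowest value in the table, made up 34.6%, 27.4% and 33.6% of the 76933 guides in FKBP5low and 35.5%, 27.6% and 23.9% in FKBP5high. The median guide had 35, 28 and 69 counts in FKBP5low and 12, 27 and 38 in FKBP5high. The top 1% of guides held 16.1%, 15.1% and 12.1% of the counts in FKBP5low against 26.7%, 25.4% and 20.4% in FKBP5high. Across guides, which are not independent replicates, libraries with the same replicate number correlated at r = 0.628 to 0.66 and libraries of the same sorted fraction at r = 0.283 to 0.308.

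**Figure D1:**
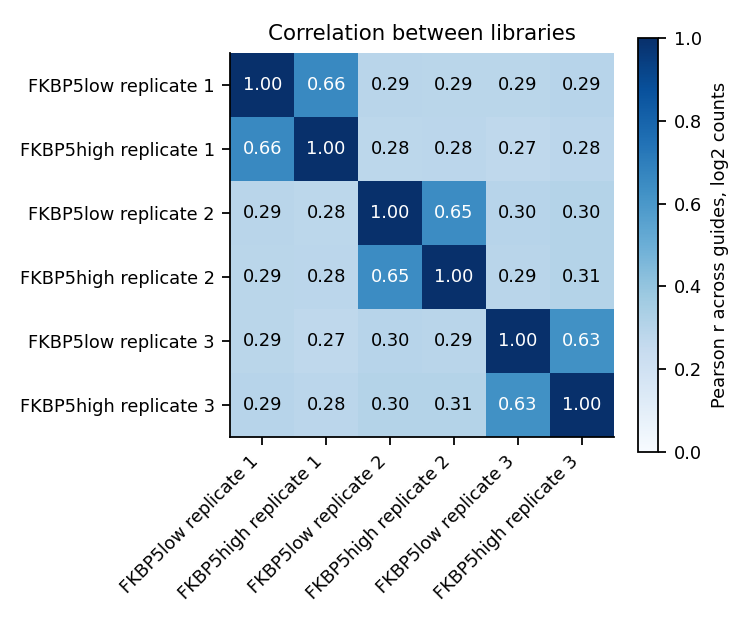
Pearson correlation of log2 counts across all guides for each pair of the 6 libraries, with darker blue for a higher r. The 3 pairs that share a replicate number lie between 0.628 and 0.66, and all other pairs between 0.271 and 0.308.

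Guides against the receptor and the stained protein itself were far more abundant in FKBP5low than in FKBP5high. For NR3C1, which encodes the glucocorticoid receptor (chromosome 5, 143277931 to 143435512, GRCh38), summed guide abundance was 573 ± 525 CPM (counts per M of the TMM-scaled total of tested guides) in FKBP5low and 4.66 ± 3.33 in FKBP5high (SD, n = 3 each), a 123-fold difference that was 57.9-fold without FKBP5low replicate 1. For FKBP5, the gene of the sorted protein (chromosome 6, 35573590 to 35728583), it was 97.3 ± 24.2 against 4.03 ± 3.08, a 24.2-fold difference. Both genes were higher in FKBP5low in 3 of 3 same-numbered pairs. Over tested guides, the log2 difference was 7.35 ± 1.14 (SE) for NR3C1 with 3 tested guides and 5.87 ± 1.07 for FKBP5 with 2. Both passed the gene test on edgeR p-values (adjusted p = 0.00269 and 0.00403), and both members of the antigen and receptor list passed adjusted over the list alone as well. The call of NR3C1 was lost without both libraries of replicate 3 (adjusted p = 0.107), where its mean guide log2 fold change was 6.36 against 7.47 with all libraries, and omitting replicate 1 or 2 left it with fewer than 2 tested guides. Without replicate 3, NR3C1-1 did not reach the filter. With all libraries kept, NR3C1 and FKBP5 lost their calls with limma on gene means (0.136 and 0.405) and with edgeR on summed counts (1 and 0.823), and FKBP5 also with the replicate block and no filter (0.0776). Over all alternatives the adjusted p ranged from 0.000806 to 1 for NR3C1 and from 0.0016 to 0.823 for FKBP5. FKBP5 lost its call without FKBP5high replicate 1 (0.103), 2 (0.0927) or 3 (0.123), with mean guide log2 fold changes of 8.0, 7.62 and 7.53 against 7.65, and the other omissions left it with fewer than 2 tested guides.

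Most single guides of the 2 genes, though not FKBP5-1, were far higher in FKBP5low. NR3C1-1 had 4292, 283 and 702 counts in FKBP5low replicates 1 to 3 and 1, 3 and 1 in FKBP5high. NR3C1-2 had 2852, 1475 and 694 against 1, 71 and 1, and NR3C1-3 had 8888, 2095 and 674 against 45, 2 and 7. NR3C1-4, with 2, 74 and 1605 against 1, 1 and 4, did not reach the filter. FKBP5-4 had 1088, 125 and 890 counts against 2, 1 and 1. FKBP5-2, with 14, 154 and 397 counts against 1 in every FKBP5high library, was at least 43.6-fold higher in FKBP5low, while FKBP5-1, with 1, 1 and 89 against 1, 1 and 58, and FKBP5-3, with 3, 1293 and 2 against 1, 63 and 4, did not reach the filter.

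Guides against STAG2, VAC14 and EHMT2 were also scarcer in FKBP5high cells. STAG2, a subunit of the cohesin ring complex that shapes chromatin loops (chromosome X, 123960560 to 124102656), had 135 ± 36.9 CPM in FKBP5low against 2.65 ± 2.42 in FKBP5high (SD, n = 3), a 50.8-fold difference that was 97.7-fold without FKBP5high replicate 3. Every STAG2 guide was at 1, the lowest value listed, in FKBP5high replicate 2, so the size of these folds is uncertain. VAC14, a scaffold of the PIKfyve lipid kinase complex on endosomes (chromosome 16, 70687439 to 70801158), had 329 ± 28.4 against 30.6 ± 23.7, and EHMT2, a histone H3 lysine 9 methyltransferase also described as a receptor coactivator (chromosome 6, 31879759 to 31897698), had 208 ± 212 against 23.9 ± 26.8. The log2 differences were 5.27 ± 1.09 (SE) for STAG2, 5.28 ± 1.04 for VAC14 and 3.54 ± 1.23 for EHMT2, and each was higher in FKBP5low in 3 of 3 pairs. With NR3C1 and FKBP5, these were the 5 of 16124 genes past the threshold in this direction (adjusted p = 0.00269 for STAG2 and VAC14, 0.00484 for EHMT2, RRA on edgeR).

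The count of 5 genes changed when libraries were left out and with the processing. It was 2, 3 and 6 without FKBP5low replicate 1, 2 or 3, and 2, 3 and 2 without FKBP5high replicate 1, 2 or 3. It was 1, 1 and 0 without both libraries of replicate 1, 2 or 3. Part of this fall was set by the filter, which was applied again to the remaining libraries. FKBP5 kept fewer than 2 tested guides without any FKBP5low library or without both libraries of any number. The same held for NR3C1 without both libraries of replicate 1 or 2, VAC14 without those of replicate 2 and STAG2 without those of replicate 3. These losses are not failed tests. STAG2 lost its call without FKBP5high replicate 1 (adjusted p = 0.143), FKBP5high replicate 2 (0.407) or both libraries of replicate 1 (0.595), with mean guide log2 fold changes of 5.78, 4.70 and 3.59 against 5.18 with all libraries. VAC14 lost it without FKBP5low replicate 1 (0.896), 2 (0.824) or 3 (0.784), without FKBP5high replicate 1 (0.271) or 3 (0.388), and without both libraries of replicate 1 (0.889) or 3 (0.947). Its mean guide log2 fold change, 5.65 with all libraries, was 5.46 and 5.72 without FKBP5high replicate 1 or 3 and 2.79 to 3.74 in the other losses. In those other losses VAC14-2 and VAC14-3, with at most 5 counts in any FKBP5high library, did not reach the filter. Nor did STAG2-2 without both libraries of replicate 1. EHMT2 lost its call without FKBP5low replicate 1 (0.229) or 2 (0.824), FKBP5high replicate 1 (0.508) or 3 (0.57), and both libraries of replicate 1 (0.595), 2 (0.835) or 3 (0.239), at 2.31 to 3.46 against 3.46. With all libraries kept, STAG2 lost its call with bias-adjusted deviances (0.0597), VAC14 with no filter (0.262) and EHMT2 with DESeq2 (0.294), no filter (0.319) or limma with the replicate block (0.375). All 3 also lost it with limma on gene means (0.743, 0.623 and 1) and with edgeR on summed counts (1 for each). Over all alternatives the adjusted p ranged from 0.00115 to 1 for STAG2 and from 0.000806 to 1 for VAC14 and EHMT2.

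**Figure D2:**
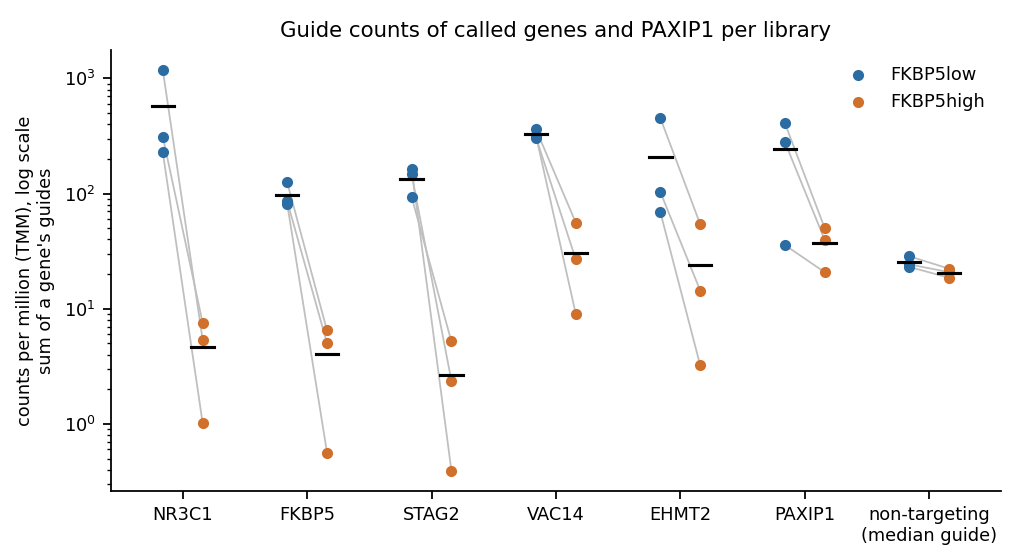
Summed guide abundance in CPM (log axis) per library for the 5 genes past the threshold and PAXIP1, and the median non-targeting guide, with grey lines joining same-numbered libraries and black bars at the group means. NR3C1 averaged 573 in FKBP5low and 4.66 in FKBP5high, while PAXIP1 averaged 243 and 37.0.

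PAXIP1, an adaptor protein of the MLL3/4 histone methyltransferase complex (chromosome 7, 154943690 to 155003411), was higher in FKBP5low in 3 of 3 pairs but did not pass. Its summed abundance was 243 ± 191 CPM against 37.0 ± 15.0 (SD, n = 3), and its log2 difference was 3.98 ± 1.16 (SE). With 2 tested guides the adjusted p was 0.298 on edgeR values, over a range of 0.0873 to 1 across its alternatives. PAXIP1-2 had 137, 1232 and 1886 counts in FKBP5low and 7, 1 and 8 in FKBP5high, and PAXIP1-3 had 348, 3878 and 2050 against 175, 511 and 492. PAXIP1-1, with 1, 57 and 327 against 1, 1 and 4, and PAXIP1-4, with 1, 1 and 283 against 1 in each, did not reach the filter. Of the STAG2 guides, STAG2-2 had 506, 1146 and 309 counts against 12, 1 and 1, STAG2-3 had 179, 18 and 190 against 1, 1 and 31, and STAG2-4 had 1320, 276 and 1005 against 7, 1 and 33. STAG2-1, with 1, 622 and 1 against 1 in each, did not reach the filter.

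With the replicate block, 12 genes passed in place of 5, and the 5 were among them. The added 7 were PTGES3, a cochaperone of HSP90 that stabilizes steroid receptors, STIP1, which links HSP70 and HSP90, MAU2, which loads cohesin onto DNA, the SAGA subunits TAF6L, TADA1 and ATXN7L3, and NF2, an upstream activator of the Hippo pathway. PTGES3 had 825 ± 444 CPM in FKBP5low against 44.5 ± 10.8 in FKBP5high (SD, n = 3), with a log2 difference of 4.75 ± 1.08 (SE). The log2 differences of the others were 4.54 ± 1.05 for MAU2, 3.30 ± 1.22 for TADA1, 3.22 ± 1.14 for STIP1, 3.17 ± 1.25 for TAF6L, 3.14 ± 1.28 for ATXN7L3 and 2.55 ± 1.12 for NF2. These SE are from the fit without the block. With the block they were 0.78 for PTGES3, 0.77 for MAU2, 0.90 for TADA1, 0.79 for STIP1, 0.83 for TAF6L, 0.93 for ATXN7L3 and 0.81 for NF2. STIP1 was higher in FKBP5low in 2 of 3 pairs and the other 6 in 3 of 3. Adjusted p-values with the block were 0.00115 for PTGES3, MAU2 and TAF6L, 0.0181 for TADA1, 0.0451 for ATXN7L3, 0.0476 for NF2 and 0.0497 for STIP1. Without it they were 0.488, 0.119, 0.0645, 0.488, 0.247, 0.208 and 0.884 in the same order. Over all alternatives, omitted libraries included, the ranges were 0.000806 to 1 for PTGES3, MAU2, TAF6L and TADA1, 0.0014 to 1 for ATXN7L3, 0.0318 to 1 for NF2 and 0.00336 to 1 for STIP1. The count with the block was 3 without both libraries of replicate 1, 1 without those of replicate 2 and 6 without those of replicate 3. The filter was applied again in these omissions, and FKBP5 could not be tested in any of them.

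No gene passed the planned test in the other direction, higher in FKBP5high. RRA on edgeR gave 0 genes, with 849 at an unadjusted p under 0.05, and 0 with the replicate block (844), RRA on DESeq2 gave 0 (785), edgeR on summed counts gave 0 (38), and limma gave 0 (78), or 1 with the block (GCA, adjusted p = 0.0192, over a range of 0.0192 to 1 across its alternatives). Limma on the authors' scaled guide values followed by RRA gave 5, among them MED16 (adjusted p = 0.00806, over a range of 0.00806 to 1 across its alternatives) and NRIP1 (0.0107, over a range of 0.0107 to 1), and the block with no filter gave 1, MED16 (0.0474). The 5 genes with the smallest p in the planned test had adjusted p-values of 0.453 to 0.469 there and did not pass it. They were GCA, which encodes the calcium-binding protein grancalcin (log2 difference -5.01 ± 1.07, SE), ARHGEF40 (-2.42 ± 1.19), PRG3 (-1.45 ± 1.04), NRIP1, a nuclear receptor corepressor also known as RIP140 (-3.24 ± 1.07), and LAMB1, a laminin chain (-2.59 ± 1.14). Each was lower in FKBP5low in 3 of 3 pairs by summed abundance. The value of PRG3 rested on 1 guide: 2 of its 3 tested guides were higher in FKBP5low, with a median guide log2 fold change of 0.3.

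**Figure D3:**
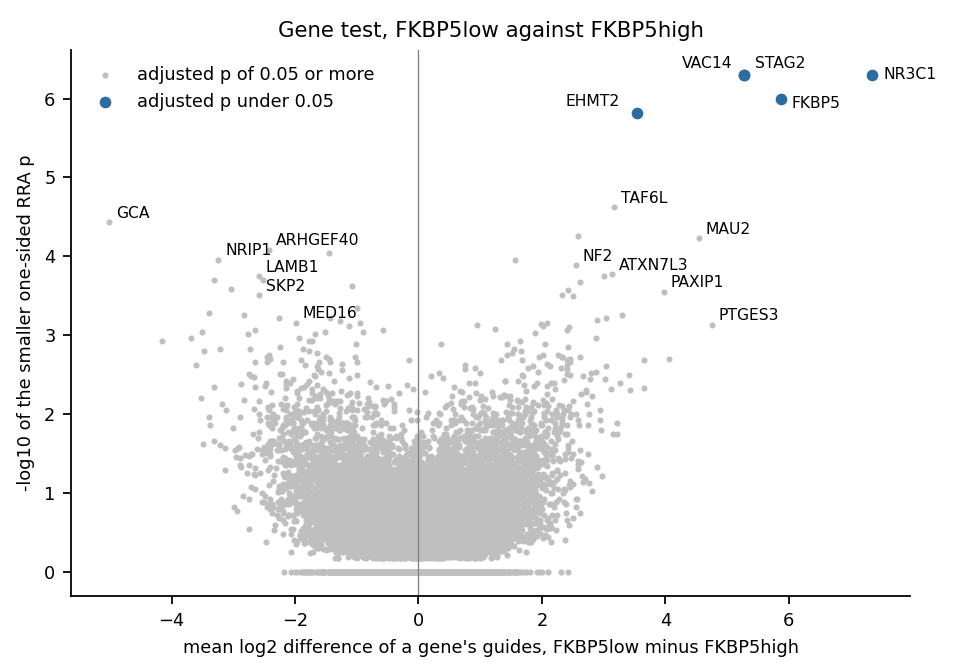
Mean log2 difference of a gene's tested guides (FKBP5low minus FKBP5high) against -log10 of the smaller 1-sided RRA p for 16124 genes, with genes of adjusted p under 0.05 in blue. The 5 blue genes lie at log2 differences of 3.54 to 7.35, and no gene on the FKBP5high side is blue.

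Single guides did not pass without the block. Of 52508 guides, edgeR called 0 higher in FKBP5low (182 at an unadjusted p under 0.05) and 0 higher in FKBP5high (198), whereas DESeq2 called 36 and 53. Fewer guides fell under 0.05 in edgeR than that level gives where nothing differs (0.73% of the guides other than controls). These p-values thus erred on the large side, and the 0 calls do not show that no guide changed. With the replicate block edgeR called 4 and 0 (640 and 919 unadjusted): VAC14-2 (adjusted p = 0.000555), NR3C1-1 (0.00323), NR3C1-3 (0.0177) and NR3C1-2 (0.0405). Those 4 guides fell to 0 without both libraries of replicate 1, 2 or 3. The filter was applied again, and VAC14-2 and NR3C1-1, with at most 3 counts in any FKBP5high library, could not be tested in any of these omissions. NR3C1-3 could not be tested without replicate 1, nor NR3C1-2 without replicate 2. For VAC14-2 and NR3C1-1 the fall to 0 therefore does not show a failure to repeat. NR3C1-3 was tested without replicate 2 or 3, and NR3C1-2 without replicate 1 or 3, and neither passed with fewer libraries. Without the block the guides with the smallest p were VAC14-2 (log2 fold change 9.64 ± 2.74, SE), NR3C1-1 (9.53 ± 2.80) and FKBP5-4 (8.41 ± 2.54) toward FKBP5low. Toward FKBP5high they were PRG3-1 (-8.06 ± 2.68), MTMR9-4 (-8.18 ± 2.76) and SLC7A5-2 (-7.12 ± 2.42). MTMR9-4 was at 1 in every FKBP5low library, so its fitted value is no bound.

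Control guides gave a background, though the non-targeting guides were not matched to the other guides in depth or spread. Their library medians were 184 to 461 counts, against 21 to 83 for olfactory receptor guides. The SD of the log2 fold changes was 0.99 for non-targeting, 1.47 for olfactory receptor and 1.48 for all other guides. The 960 tested non-targeting guides had a median log2 fold change of 0.03, and 51.5% were higher in FKBP5low. By edgeR, 0 had an unadjusted p under 0.05 (95% Wilson interval 0.0% to 0.4%) and 0 passed. DESeq2 called 0 as well. With the replicate block 13 (1.35%) had an unadjusted p under 0.05, their median was 0.18, and 0 passed. The share was 0.11% without FKBP5low replicate 1, 0.32% without FKBP5low replicate 2, 0.53% without FKBP5high replicate 2 and 0.21% without FKBP5high replicate 3. Guides against olfactory receptors, which are not expected to act in lung cells, had a median of 0.02 over 1075 guides, with 12 (1.12%) at an unadjusted p under 0.05, or 26 (2.42%) with the replicate block, 0 past the threshold in edgeR and 4 in DESeq2. Of the 50473 other tested guides, 368 (0.73%) had an unadjusted p under 0.05 by edgeR, or 1520 (3.01%) with the replicate block. The olfactory receptor list as a whole, 341 genes, had a mean log2 difference of -0.02 and a median of 0.02 (camera adjusted p = 0.894), with 0 genes past the threshold over all genes or adjusted over the list alone.

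Several chromatin complexes were higher in FKBP5low as groups. Among 25 fixed lists, camera called 4 higher in FKBP5low and 1 higher in FKBP5high. With an estimated correlation none of the 5 passed, and fry called 0. The 5 lists became 3 without FKBP5low replicate 2, 2 without FKBP5high replicate 2, 3 without FKBP5high replicate 3 and 1 without both libraries of replicate 1. The SAGA coactivator complex, which acetylates and deubiquitinates histones, had 14 of 17 genes higher in FKBP5low with a mean log2 difference of 1.39 (adjusted p = 1.68e-07, and adjusted p = 0.123 with an estimated correlation). None of its genes passed over all genes, 6 passed adjusted over the list alone and 3 passed over all genes with the replicate block. The 6 were TAF6L, ATXN7L3 and TADA1 and, chosen after their values were seen, TADA2B, TAF5L and TAF12. The list kept its call in all 9 omissions of libraries (adjusted p = 1.74e-08 to 0.000452). Fry called it with the replicate block (adjusted p = 0.0443), and its alternatives ranged from 1.7e-11 to 0.457.

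The MLL3/4 complex, which methylates histone H3 lysine 4 at enhancers, had 4 of 6 genes higher in FKBP5low with a mean log2 difference of 1.77 (camera adjusted p = 5.39e-05, and adjusted p = 0.123 with an estimated correlation). None passed over all genes, and 3 passed adjusted over the list alone: PAXIP1, KMT2D, a catalytic subunit (2.87 ± 1.18, SE), and PAGR1, the partner of PAXIP1 (2.96 ± 1.04). KMT2C and KDM6A, chosen after their values were seen, had log2 differences of -0.19 and -0.15. The call was lost without both libraries of replicate 1 (adjusted p = 0.123), and the alternatives ranged from 5.21e-07 to 0.457. The cohesin and CTCF list had 9 of 11 genes higher in FKBP5low with a mean of 1.39 and a median of 0.41 (adjusted p = 5.39e-05, and adjusted p = 0.461 with an estimated correlation). STAG2 passed over all genes, joined by MAU2 with the block, and 4 passed adjusted over the list alone: STAG2, MAU2, the ring subunit RAD21 (2.51 ± 1.23) and, chosen after its values were seen, SMC1A. The log2 difference of SMC1A over its tested guides was only 0.35. Its call was lost without FKBP5high replicate 2 (0.0564) and without both libraries of replicate 1 (0.676), and its alternatives ranged from 2.26e-06 to 0.676.

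Receptor chaperones had 8 of 14 genes higher in FKBP5low with a mean log2 difference of 0.72 (camera adjusted p = 0.0466, and adjusted p = 0.7 with an estimated correlation). With the replicate block the list missed the threshold (0.0633, over a range of 0.00139 to 0.935 across its alternatives), and 2 of its genes, PTGES3 and STIP1, passed over all genes. PTGES3 passed adjusted over the list alone, and DNAJA1, an HSP70 cochaperone, had a log2 difference of 1.82 ± 1.11 (SE). The list lost its call without FKBP5low replicate 1 (0.935) or 2 (0.112), FKBP5high replicate 2 (0.173) or 3 (0.393), or both libraries of replicate 1 (0.0916). The EGFR-RAS-MAPK pathway ran the other way, with 6 of 18 genes higher in FKBP5low and a mean of -0.64 (adjusted p = 0.0438, and adjusted p = 0.361 with an estimated correlation, over a range of 0.0095 to 0.865 across its alternatives). None of its genes passed over all genes or adjusted over the list alone. Its examples were GRB2, an adaptor of receptor kinases (-2.12 ± 1.19, SE), and RASA2, a GTPase-activating protein (-1.62 ± 1.12). This call was lost without FKBP5low replicate 1 (0.0645), 2 (0.421) or 3 (0.0592), FKBP5high replicate 1 (0.36), 2 (0.1) or 3 (0.359), and both libraries of replicate 1 (0.302), 2 (0.12) or 3 (0.865).

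**Figure D4:**
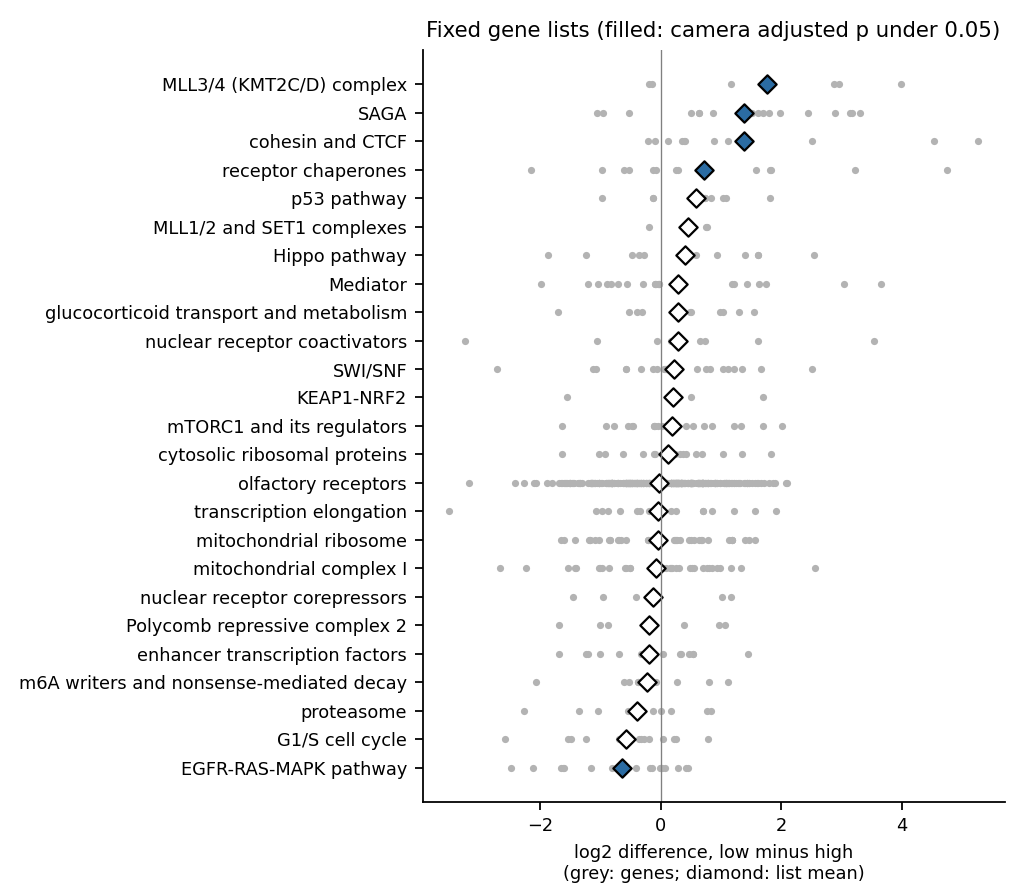
Log2 differences (FKBP5low minus FKBP5high) of the tested genes of 25 fixed lists (grey points) and list means (diamonds, filled blue where the camera adjusted p was under 0.05). List means run from -0.64 for the EGFR-RAS-MAPK pathway to 1.77 for the MLL3/4 complex.

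The remaining lists did not pass as groups, and some held single genes past the threshold adjusted over the list alone. Nuclear receptor coactivators (10 genes, mean log2 difference 0.28, camera adjusted p = 0.704) held EHMT2, past the threshold over all genes, and NRIP1 in the other direction, while EHMT1, the partner of EHMT2, had 1.62 ± 1.13 (SE). Mediator (22 genes, mean 0.29, median -0.07, adjusted p = 0.612) held CCNC, the cyclin of its kinase module (3.04 ± 1.17), toward FKBP5low and MED16, a tail subunit (-1.98 ± 1.04), toward FKBP5high; MED12 of the kinase module had 3.66 ± 1.12. The Hippo pathway (12 genes, 0.4, 0.405) held NF2 toward FKBP5low. Toward FKBP5high, the G1/S cell cycle list (17 genes, -0.57, 0.13) held SKP2, a ubiquitin ligase subunit that targets cell cycle inhibitors (-2.58 ± 1.52). The direction of SKP2 turned without FKBP5high replicate 1 (mean guide log2 fold change 0.31, adjusted p = 1). Polycomb repressive complex 2 (7 genes, -0.19, 0.864) held EED (-1.68 ± 1.61), and transcription elongation (18 genes, -0.04, 0.893) held SUPT5H (-3.51 ± 1.07).

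In the other lists no gene passed, over all genes or adjusted over the list alone. The p53 pathway had a mean log2 difference of 0.58 over 12 genes (camera adjusted p = 0.13), and the MLL1/2 and SET1 complexes had 0.46 over 4 genes (0.644). Glucocorticoid transport and metabolism had 0.29 over 10 genes (0.644), SWI/SNF 0.22 over 25 (0.644), KEAP1-NRF2 0.2 over 4 (0.864) and cytosolic ribosomal proteins 0.13 over 17 (0.864). The mTORC1 list had a mean of 0.19 and a median of -0.01 over 20 genes (0.646). Nuclear receptor corepressors had -0.12 over 6 genes (0.864), enhancer transcription factors -0.2 over 16 (0.704), m6A writers and nonsense-mediated decay -0.22 over 11 (0.805) and the proteasome -0.39 over 10 (0.644). Mitochondrial complex I had a mean of -0.07 and a median of 0.12 over 34 genes (0.864). The mitochondrial ribosome had a mean of -0.04 over 41 genes, although camera ranked it toward FKBP5low (0.982).

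The authors' deposited table, made with MAGeCK on pooled replicates, lists 6 genes higher in FKBP5low at a false discovery rate under 0.05 among 19113 entries. In the authors' deposited table NR3C1 and STAG2 stand at 0.00248, PAXIP1 at 0.00825, and FKBP5, VAC14 and MAU2 at 0.014. Of these 6, 4 passed here without the block, where PAXIP1 and MAU2 did not, and 5 with it, where PAXIP1 alone did not. EHMT2, which passed here, stands at 0.0545 in the authors' deposited table. Toward FKBP5high the authors' deposited table has 0 genes under 0.05, and the lowest rate is 0.0941, for LAMB1.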

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

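Tests with counts minus 1, with bias-adjusted deviances and with the replicate block combined with another choice were chosen after the data had been seen. The direction of a gene was taken as the mean over its tested guides, also after seeing that the median of PRG3 ran against its test; by the median, PRG3 points to FKBP5low. In simulated counts 28.7% of genes with a log2 fold of 4 were recovered without the replicate block and 50.6% with it. The cause of each change below was not tested.

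Guides past the threshold, 0 and 0 in edgeR, were 36 toward FKBP5low and 53 toward FKBP5high with DESeq2, 4 and 0 with the replicate block, and 1 and 0 with the authors' scaled values under either pseudocount. They were 0 to 0 in each direction when libraries were left out. Genes higher in FKBP5low, 5 in the test as planned, were 3 with no filter, 8 with at least 50 counts, 12 with the replicate block, 12 at an adjusted p under 0.25, and 13 and 13 with the authors' scaled values plus 1 or 10. They were 0 with limma on gene means and 0 with edgeR on summed counts. With the replicate block they were 13 with no filter, 13 with the mean guide z, 6 with limma on gene means, 0 with edgeR on summed counts, 3 without number 1 and 1 without number 2. Leaving out libraries, with the count filter applied again to the rest, gave 0 to 6. Some of the 5 genes then had fewer than 2 tested guides and could not be called. Genes higher in FKBP5high, 0 as planned, were 5 and 5 with the authors' scaled values (MED16 and NRIP1 among them), 1 with the replicate block and no filter (MED16, adjusted p = 0.0474), 1 with the replicate block and limma (GCA), and 0 to 0 without single libraries.

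The adjusted p of NR3C1 was 0.136 with limma, 1 with summed counts and 0.00242 to 0.107 over the 7 omissions that left at least 2 tested guides. That of FKBP5 was 0.405 with limma, 0.823 with summed counts, 0.0776 with the replicate block and no filter, and 0.0927 to 0.123 over the 3 omissions that left 2 tested guides; at 50 counts it could not be tested. The share of non-targeting guides at an unadjusted p under 0.05, 0.0%, was 0.6% with no filter, 1.35% with the replicate block, 1.61% with the block and no filter, 1.41% with the block without number 1, and 0.0% to 0.53% over the omissions.

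Fixed lists past the threshold, 5 with camera, were 3 with no filter, 3 with the authors' scaled values plus 1, 3 with a prior count of 0.5, 0 with an estimated correlation and 0 with fry. With the replicate block they were 1 without number 1, 0 with an estimated correlation and 1 with fry. Omissions gave 1 to 4. The replicate block changed the call of the receptor chaperones list and of no other list.

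Outside the counts, 2 named genes turned direction, neither of which had passed. PRG3 did so with at least 50 counts (adjusted p toward FKBP5high = 1), without FKBP5high replicate 2 or 3 or both libraries of replicate 3 (1 to 1), and with the replicate block without number 3 (1), over ranges of 0.373 to 1 across its alternatives with all libraries or with the block and 0.868 to 1 over its omissions. SKP2 did so without FKBP5high replicate 1 (1), within 0.34 to 1 over its omissions.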

Other observations

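The gene groups in the first paragraph, the test of reads and of the share of guides at 1, and the splits for guides and genes were chosen after the results had been seen. The fits without the block that left out a replicate number or the filter were set before the data were examined. Their use below to weigh an explanation was chosen after the results had been seen. Of the PIKfyve complex, grouped because VAC14 passed, 3 of 3 genes were higher in FKBP5low: besides VAC14, the phosphatase FIG4 had a log2 difference of 3.21 ± 1.31 (SE) and the kinase PIKFYVE 0.86 ± 1.22, and neither passed the gene test (adjusted p = 0.898 and 1). The HUSH silencing complex and its partners ran the other way, with 0 of 6 genes higher in FKBP5low and a mean log2 difference of -1.11 over a range of -1.82 to -0.6. Its camera adjusted p was 0.00173, and the adjusted p was 0.0436 with an estimated correlation. Within SAGA, the acetyltransferase module had 4 of 4 genes higher in FKBP5low (mean 1.93) and the core module 7 of 8 (1.64), whereas the deubiquitinase module had 2 of 4 (0.57); the difference between modules was not tested. The Mediator kinase module had 4 of 6 genes higher in FKBP5low with a mean of 1.12 (adjusted p = 0.00685, and adjusted p = 0.0765 with an estimated correlation). All of these groups were formed on the same values that they describe, so their p-values are no independent test.

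Guides against genes that most cell lines need were rare in all 6 libraries. Of 325 guides against cytosolic ribosomal proteins, 67 (20.6%) reached the filter, as did 41 of 151 (27.2%) against the proteasome, 123 of 311 (39.5%) against the mitochondrial ribosome and 96 of 192 against mitochondrial complex I. The share was 72.1% for olfactory receptors and 96.2% for non-targeting guides. The screen therefore says little on these essential complexes. The labels state a 500x coverage, and 3500000 cells over 76933 guides come to 45.5 cells per guide in a sorted fraction. A sorted fraction is a 7.5% tail of the stained cells, so the 2 figures need not describe the same population.

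Guide counts were uneven between libraries: of 76933 guides, 46930 (61.0%) were above 1 in all 3 replicate numbers. Too few reads would leave little spread beyond counting, yet the dispersion of the non-targeting guides with the replicate block stayed at 0.543 or more whichever number was left out. So for non-targeting guides too few reads alone do not account for the spread. Their library medians were 184 to 461 counts, against 12 to 69 over all guides. The part of reads in the unevenness of thinly counted guides therefore stays open. The dispersion test was added after another, the share of non-targeting guides with at least 100 counts in one library that were at 1 in its partner, had left the matter undecided. Those shares were 1.28%, 0.48% and 0.93% for numbers 1, 2 and 3, on both sides of the 1% set for the test, so a small number of cells or template molecules per guide stays open. A separate population of infected cells behind each replicate number may contribute, since same-numbered libraries correlated over non-targeting guides by at least 0.339 more than differently numbered ones; no biological explanation was tested.

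The SAGA, MLL3/4 and cohesin lists were higher in FKBP5low. Low mean abundance of their genes is an unlikely cause, since 0.0% of 10000 random lists matched on abundance and size reached the mean of SAGA, and the same held for the other 2 lists. The random lists were not matched on the number of tested guides or on counts at 1. Only lists that camera had called were compared, so this is no independent test of their difference. A single replicate number does not account for SAGA, whose highest adjusted p without 1 number was 5.92e-05, but replicate 1 stays open for MLL3/4 (0.123 without it) and cohesin (0.676). With an estimated correlation the adjusted p rose to 0.123 for SAGA (estimate 0.024) and 0.461 for cohesin (0.327), but also to 0.123 for MLL3/4, where the estimate of -0.105 lies below the preset 0.01. For MLL3/4 the rise therefore does not show correlation among its genes. For cohesin, whose estimate lies far above the preset, correlation may contribute. What else changes between the 2 forms of the test was not examined, and no biological explanation was tested.

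PAXIP1 stands at 0.00825 in the authors' deposited table and had an adjusted p of 0.298 here. The filter on low counts left 2 of its 4 guides. Dropping the filter alone did not bring PAXIP1 under the threshold in the gene test (adjusted p = 0.262). The same fit also took VAC14 from 0.00269 to 0.262 and EHMT2 from 0.00484 to 0.319. All guides of those 2 genes had passed the filter, so this fit changes more than the guides of PAXIP1. It cannot isolate the part of the filter, which stays open. With all guides ranked by their pooled ratio, the same gene test gave PAXIP1 an adjusted p of 0.00318. That ranking pools the replicates, replaces the edgeR p by a ratio and drops the filter at once, so the part of pooling alone was not tested and stays open. It called 4 genes, FKBP5, NR3C1, PAXIP1 and STAG2, at most 1 gene in any other split of the libraries, and not VAC14 or MAU2, which the authors' deposited table has at 0.014.

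The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 genes and the highest of the others 1, 0 guides against 0 (all 10 splits), and 5 fixed lists against 2. Among the 4 splits that part all 3 pairs, also too few, the real one gave 12 genes with the replicate block and the highest of the others 2.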
